A study of Mus musculus with 30 samples.

How the data were processed

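RNA of Sox1-GFP mouse ES cells and of their SFEB aggregates on days 1 to 5 was measured in 10 samples of 8 groups, as biotin-labelled cRNA on the 3 chips of the Affymetrix U74 version 2 set (A, B and C), 30 arrays in all. The deposited values were 1 linear intensity per probe set and array, and as deposited they were already scaled: the 2% trimmed mean of each array lay between 499.868 and 499.921. The software and the background correction are not given in the sources used here. The chips held 36899 probe sets (12488, 12477 and 11934), of which the 198 control probe sets were left out. Of the others 29197 named 1 gene, 724 several and 6846 none in the platform's probe-to-gene tables. Symbols were updated by Entrez ID to the RefSeq names of GRCm38.p6, which was used for names alone. Probe sets with several symbols or none were tested and counted but not named.

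The values were used as deposited, since the medians of log2 values over the 10 arrays of a chip lay within 0.25 of each other (0.181, 0.249 and 0.165). They were analysed as log2 of the intensity plus 16, a scale that understates the changes of genes with low signals. Probe sets were tested if their mean intensity reached the 30th percentile of their chip (78.6, 117 and 102), which left 25690 (8695, 8688 and 8307). The medians of intensity per array ranged from 176 to 202, 231 to 277 and 195 to 220 on the 3 chips. The number of arrays limits the precision, as 7 of 8 groups had 1 sample each. For results per gene, 1 probe set was kept for each of 12932 genes, the one with the highest mean log2 value among those naming that gene alone.

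Sox1-positive cells of days 3, 4 and 5 (3 samples) were compared with ES cells (3 samples) by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on each chip and Benjamini-Hochberg adjustment over the 3 chips together; an adjusted p under 0.05 was called. The lone samples of day 1, day 2 (each sort) and day 3 (Sox1-negative) were compared with the ES cells in a limma fit of 8 groups, where the spread comes from the ES samples. A slope on day was fitted among the Sox1-positive samples. The sorts of day 2 and of day 3 had 1 sample on a side and got no test: probe sets differing by 1 or more on the log2 scale were counted beside the counts between ES samples. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The limma code was tested on simulated data, with 300 probe sets changed by each of 1 and 2 on the log2 scale. It recovered 40.3% and 92% of them in the comparison of 3 with 3 samples (5.25% of the calls were false). For a lone sample it recovered 3.33% and 59.7% (5.97%), and for the slope 56% and 96.7% (4.18%). Every simulated array had independent noise with the spread of the ES samples, and the slopes were exactly linear. The shares need not hold for the real samples, whose variation between days and cultures was not simulated.

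There were 31 gene lists with 542 genes, written from general knowledge before the data were examined, as were the comparisons, the tests and the rule for naming genes: pluripotency, primed epiblast, neural progenitor, anterior neural, mid-hindbrain and caudal, neuronal, mesoderm and primitive streak, endoderm, surface ectoderm and trophectoderm, neural crest, fibroblast, blood and endothelium, germ cell and two-cell-like, epithelial, mesenchymal, cell cycle, glycolysis, hypoxia response, cholesterol synthesis, oxidative phosphorylation, imprinted, nodal, BMP, Wnt, Notch, FGF-ERK, retinoic acid, hedgehog, immediate early and heat shock, p53, and chromatin and DNA methylation. Lists were tested in limma's camera with a preset correlation of 0.01 between genes and, beside it, with an estimated correlation. For lone samples the median of a list was placed among 10000 random lists of the same size, matched in 5 bins of signal per chip. A list of LIF and STAT3 targets and a list of floor plate and ventral neural tube genes were added later.

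Sox1, Cdh1 and Pou5f1 were always named. In the comparison of 3 with 3 samples the 12 largest rises and falls that were called with no overlap of arrays were named, and the 2 largest rises and falls called in each list. Against ES cells the 8 largest each way that were called would be named for a lone sample and for the slope. Between sorts the 10 largest each way were named among genes whose higher value reached the chip's median, and from the lists the 2 largest each way could be drawn on. Other genes were chosen after their values were seen, and the text says where.

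Alternatives tried were quantile normalization, scaling to the 75th percentile, pseudocounts of 1 and 64, no filter or one at the 60th percentile, leaving out each array in turn, a mean-variance trend in the prior, adjustment within each chip, a further threshold of 1 on the log2 scale (2 for the sorts), a slope on day in the comparison of 3 with 3 samples, the mean over all probe sets of a gene and, for lists, an estimated correlation. Leaving out ES 3 and day 5 together was added after the data were seen.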

Results

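Gene expression was measured in mouse embryonic stem (ES) cells of a 129-derived Sox1-GFP line, in which a green fluorescent protein reports the neuroectodermal gene Sox1. The cells were differentiated as serum-free floating aggregates (the SFEB culture) for 1 to 5 days and sorted by flow cytometry. There were 3 ES samples, sorted as E-cadherin-positive, and 1 sample each of day 1 cells with no sort label, day 2 E-cadherin-positive, day 2 E-cadherin-negative, day 3 Sox1-negative and day 3, day 4 and day 5 Sox1-positive cells. Each of the 10 samples was hybridised to the 3 chips of the Affymetrix U74 version 2 set, which gave 30 arrays. The deposited value was a linear intensity per probe set, and its median per array lay between 176 and 277. The number of arrays limits the precision. Only ES cells had replicates, and nothing in the labels says whether these were separate cultures. The p-values measure the spread between these samples alone, which among the ES samples may be technical. The 3 Sox1-positive samples were of different days, so their spread and SD also hold the change from day 3 to day 5. The 3' to 5' signal ratio of the actin control probe sets, a measure of RNA integrity, was highest in ES 3 (1.70 on U74Av2). It was 1.34 on day 5 and 1.33 in the day 2 E-cadherin-negative sample, against 0.939 to 1.15 in the other samples on that chip.

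Sox1-positive cells of days 3 to 5 were compared with ES cells to show what the sorted neuroectodermal cells gained and lost. They had lost most of the pluripotency programme and carried high signals of many neural progenitor genes. Esrrb (probe set 168508_at), a nuclear receptor of the ES cell network, fell from an intensity of 13470 ± 3157 (SD, n = 3) to 103 ± 35.9 (n = 3), a log2 change of -6.85 with a limma adjusted p of 0.000158. Crabp1 (98108_at), a cytoplasmic retinoic acid-binding protein, rose from 318 ± 31.2 to 8793 ± 3307, a log2 change of 4.64 with a limma adjusted p of 0.000194. Nr2f1 (102715_at), a nuclear receptor of the developing nervous system, rose from 22.8 ± 15.5 to 2163 ± 1711, a log2 change of 5.59 with a limma adjusted p of 0.00107. Limma called 2710 of 25690 probe sets at an adjusted p under 0.05, 1467 higher and 1243 lower. They gave 1626 of 12932 genes, 828 higher and 798 lower, and in all 1626 the 3 Sox1-positive arrays lay outside the range of the 3 ES arrays. Over all genes tested, 35.1% had no overlap of arrays, against 10% by chance. The count of probe sets was 1233 without ES 2, 1681 without ES 3, 1290 without the day 4 arrays and 1055 without ES 3 and day 5 together, the samples with the highest actin ratios (the last chosen after seeing the data).

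The 12 largest rises, by log2 change, were Ednrb (163124_s_at, 5.78), an endothelin receptor, Nr2f1 (5.59), the neural POU factor Pou3f3 (163586_at, 4.65), Crabp1 (4.64), the imprinted neuronal gene Nnat (97520_s_at, 4.56), the transcription factor Dach1 (114999_at, 4.45), the adhesion receptor Adgrv1 (167583_at, 4.37), Cracd (130957_f_at, 4.18), the ligand Wnt7a (166857_s_at, 4.08), Crabp2 (100127_at, 4.01), the receptor-type phosphatase gene Ptprn2 (113747_at, 3.87) and the cyclin Ccnd2 (97504_at, 3.86). The 12 largest falls were Esrrb (-6.85), Mymx (167088_r_at, -6.22), the T-box factor Tbx3 (166427_f_at, -5.87), the zinc finger gene Zfp42 (98414_at, -5.87), Dusp27 (166748_at, -5.46), the F-box gene Fbxo15 (96162_at, -5.20), the epithelial factor Grhl3 (165713_at, -4.72), Mreg (107952_i_at, -4.66), the homeobox gene Rhox5 (101368_at, -4.45), Eprn (133385_at, -4.42), the glycosyltransferase B3gnt2 (160137_at, -4.38) and the inositol phosphatase Inpp5d (102884_at, -4.38). Limma adjusted p ranged from 6.3e-05 for Inpp5d to 0.0412 for Adgrv1, and standard errors from 0.182 for Inpp5d to 1.04 for Adgrv1. In genes with a low signal on one side the size depends on the pseudocount: Nr2f1 had 6.44 with a pseudocount of 1 and 4.41 with 64, and Tbx3 -7.56 and -4.25. The call of Cracd ended without the day 4 arrays (its highest adjusted p over the alternatives was 0.0508) and that of Mymx without ES 3 and day 5 together (0.0528). The call of Wnt7a ended without ES 1, ES 2, ES 3, day 4 or day 5, with no filter and with adjustment within each chip (highest adjusted p 0.125), and that of Adgrv1 without ES 2, day 3, day 4 or day 5, with a pseudocount of 1, with no filter and with adjustment within each chip (0.117).

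**Figure D1:**
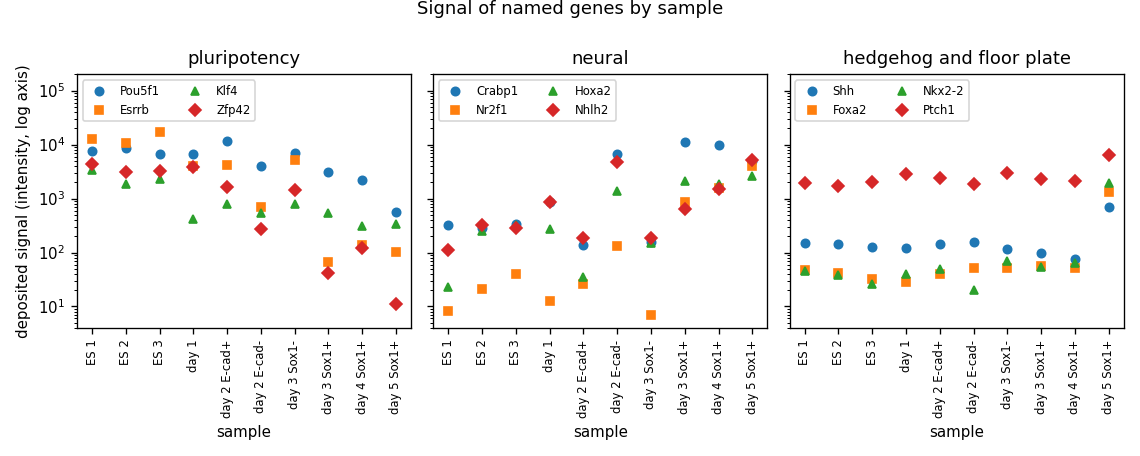
Deposited intensity (log axis) of 4 pluripotency, 4 neural and 4 hedgehog or floor plate genes in each of the 10 samples; each point is 1 array. Esrrb fell from a mean of 13470 in ES cells to 103 in Sox1-positive cells, Crabp1 was high on the day 2 E-cadherin-negative array (6659) and the Sox1-positive arrays, and Nkx2-2 reached 1908 on day 5 only.

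The genes behind the sorts behaved differently from each other. Sox1 (92342_at) rose from 156 ± 17.2 to 290 ± 33.1 (n = 3 each), a log2 change of 0.83 with a limma adjusted p of 0.0229. Its call ended without ES 2, ES 3, day 3 or day 4 (highest adjusted p 0.0954). Cdh1 (98140_at), which encodes E-cadherin, had 577 ± 137 in ES cells and 425 ± 25.8 in Sox1-positive cells, a log2 difference of -0.40 that did not pass (limma adjusted p 0.282). Pou5f1 (103075_at), the gene of the pluripotency factor Oct4, fell from 7728 ± 980 to 1972 ± 1297, a log2 change of -2.26 with a limma adjusted p of 0.0351. Its signal was 3139 on day 3, 2203 on day 4 and 575 on day 5, and its call ended without ES 1, ES 2, ES 3 or day 4 and with no filter (highest adjusted p 0.126).

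Genes of the lists that are given without a probe set were chosen after their values were seen. Of the 32 pluripotency genes tested, 25 fell, 0 rose and 7 did not pass in limma (29 fell when adjusted over the list alone), with a median log2 change of -2.71. Besides Esrrb and Tbx3, the falls included the transcription factor gene Tfcp2l1 (-4.14), the nuclear receptor Nr0b1 (-3.85) and the Krüppel-like factors Klf5 (-3.38), Klf2 (-3.34) and Klf4 (-2.60). Sox2, a factor shared by ES cells and neural progenitors, had a log2 difference of -0.37 (limma adjusted p 0.279), and Nanog had -2.23 (0.0933). The list was low as a set in limma's camera test (adjusted p 2.88e-52), with an adjusted p of 0.108 with an estimated correlation. Of the 10 germ cell and two-cell-like genes, 6 fell (6 when adjusted over the list alone), among them the meiotic gene Stra8 (101194_at, -2.62) and Dppa3 (97283_at, -2.15). Camera gave an adjusted p of 9.1e-05, and 0.124 with an estimated correlation. The 15 genes of the primed epiblast moved both ways, with 5 that rose and 2 that fell (6 and 3 when adjusted over the list alone). Cd24a (100600_at, 2.78) and Sox3 (103302_r_at, 2.62) rose, and the tight junction gene Cldn6 (163262_at, -2.29) and Zic5 (116403_at, -1.62) fell. Its camera adjusted p was 0.0337, 0.896 with an estimated correlation and 0.237 with the mean over the probe sets of a gene. The epiblast list did not keep its sign over the days: its median against ES cells was 0.65 on day 3, 0.47 on day 4 and -0.65 on day 5. Of the germ cell genes, 3 fell without ES 2 or day 3 and 2 without day 4 or day 5. Without ES 2, and without ES 3, 1 epiblast gene fell. The call of Cldn6 ended without ES 2, ES 3 or day 5 (highest adjusted p 0.124) and that of Dppa3 without ES 2, day 3, day 4 or day 5 (0.0752).

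Of the 37 neural progenitor genes, 26 rose, 0 fell and 11 did not pass in limma (28 rose when adjusted over the list alone), with a median log2 change of 2.31. Next to Nr2f1, Pou3f3 and the Crabp genes, the rises included Cdh2 (3.42), the neural cadherin, the Wnt antagonist Sfrp1 (3.28), Sox21 (2.74), Pax6 (1.56) and the intermediate filament gene Nes (1.18). Hes5, Sox9 and Vim had log2 differences of -0.08, -0.01 and -0.20 (limma adjusted p 0.889, 0.981 and 0.702). The camera adjusted p was 7.31e-35, and 0.1 with an estimated correlation. Of 18 mid-hindbrain and caudal genes, 8 rose and 0 fell (9 rose when adjusted over the list alone). These were the hindbrain genes Hoxa2 (171063_at, 3.83), Hoxa3 (163890_at, 3.37), Hoxb2 (3.05), Hoxb4 (2.05), Hoxb1 (1.86) and Egr2 (1.57), with Irx3 (3.30) and Meis2 (2.31). The midbrain genes En1 and En2 had 0.56 and 0.60 (limma adjusted p 0.377 and 0.347). The camera adjusted p was 9.4e-09, and 0.124 with an estimated correlation. Of 5 anterior neural genes tested, of 16 listed, Zic1 (104169_at, 2.62) and Fezf2 (92229_at, 0.97) rose (2 when adjusted over the list alone; camera adjusted p 0.0244, and 0.298 with an estimated correlation). Of 23 neuronal genes, 4 rose and 0 fell (7 rose when adjusted over the list alone), among them the neurofilament gene Nefm (117269_at, 2.75) and the RNA-binding protein gene Elavl4 (163986_at, 2.37), with a median of 0.37 (camera adjusted p 0.0244, and 0.496 with an estimated correlation). Of 10 retinoic acid response genes, 5 rose and 1 fell (the same counts when adjusted over the list alone). Crabp1, Crabp2, Hoxb1, the retinoic acid-degrading enzyme gene Cyp26a1 (1.33) and Nrip1 (1.09) rose, and the receptor Rarg (102419_at) fell by 3.83 (camera adjusted p 3.7e-05, and 0.298 with an estimated correlation).

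These neural counts depended on single samples. Without ES 2, 17 neural progenitor, 4 mid-hindbrain, 1 neuronal, 1 anterior neural and 3 retinoic acid response genes rose. Without day 4, 5 mid-hindbrain, 1 anterior neural and 3 retinoic acid response genes rose, and without day 5, 5 mid-hindbrain and 1 anterior neural. Without ES 1, and without ES 3, 1 neuronal and 1 anterior neural gene rose. The calls of Hoxa2 and Hoxa3 ended without ES 2, day 3, day 4 or day 5 (highest adjusted p 0.0783 and 0.0824), and that of Hoxa2 also with adjustment within each chip. The call of Elavl4 ended without each ES array (0.0775), and that of Fezf2 in 11 of the alternatives, including quantile normalization and leaving out ES 1, ES 2, ES 3, day 4 or day 5 (0.146).

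**Figure D2:**
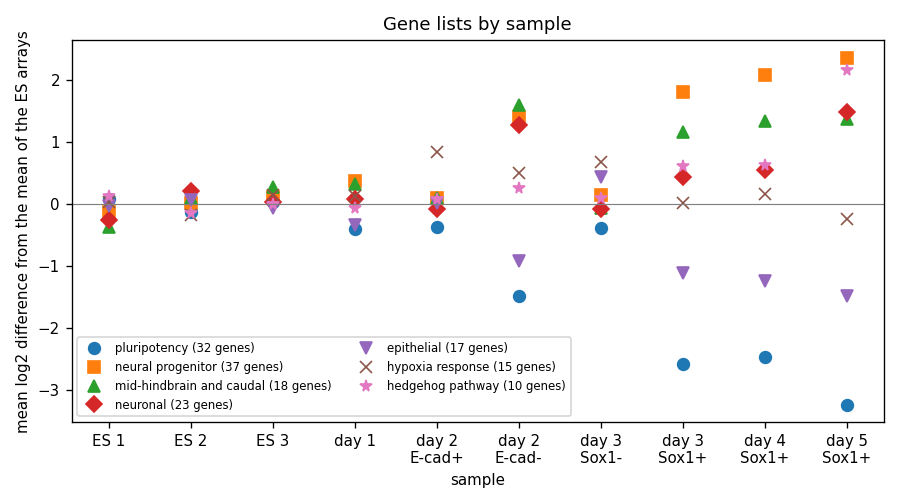
Mean log2 difference from the mean of the 3 ES arrays, over the tested genes of 7 lists, in each of the 10 samples; each point is 1 list in 1 sample. The pluripotency list had means of -2.58, -2.47 and -3.23 on days 3, 4 and 5 in Sox1-positive cells and -1.48 in day 2 E-cadherin-negative cells, while the hedgehog list was highest on day 5 (2.17).

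Epithelial genes fell: 8 of 17 passed in limma, 0 rose and 9 did not pass (11 fell when adjusted over the list alone), with a median log2 change of -1.16. The claudin Cldn4 (101410_at, -3.68), plakoglobin (Jup, 104121_at, -2.46), the desmosomal gene Pkp2 (-2.26) and the transcription factor Grhl2 (164027_at, -1.96) fell, whereas the adhesion gene Epcam had 0.23 (limma adjusted p 0.66). The camera adjusted p was 5.1e-08, and 0.124 with an estimated correlation. Of 9 mesenchymal genes, 2 rose (2 when adjusted over the list alone), both cadherins: Cdh2 (102852_at) rose from 244 ± 58.8 to 2737 ± 503, and Cdh11 (139147_at, 2.74) rose too. Vim, Fn1 and Snai2 had -0.20, -0.28 and -0.20 (limma adjusted p 0.702, 0.385 and 0.516). The camera adjusted p was 0.00596, and 0.298 with an estimated correlation. Of 12 surface ectoderm and trophectoderm genes, Tfap2c (92275_at, -4.12) and Grhl2 fell (2 when adjusted over the list alone; camera adjusted p 0.0122, and 0.332 with an estimated correlation). The epithelial falls were 4 without ES 2, 5 without ES 3 and 5 without day 5. Without ES 1, 4 surface ectoderm genes fell.

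Lists of the other germ layers and of cells the samples could hold did not pass camera. Of 15 mesoderm and primitive streak genes, Bmp4 (93455_s_at, -0.93) fell and 0 rose (camera adjusted p 0.823). Of 21 endoderm genes, the laminin gene Lamc1 (161706_f_at, -1.32) fell and 0 rose (0.823). Of 12 neural crest genes, Ednrb rose. In that list the receptor Erbb3 (96771_at, -2.66) and Foxd3 (92889_r_at, -1.23) fell (0.486). None of the 11 fibroblast or feeder genes and none of the 5 blood and endothelium genes passed in limma (0.898 and 0.817). Adjusted over the list alone, the counts were 1 fall for mesoderm, 1 fall for endoderm, 1 rise and 3 falls for neural crest, and 0 for the others. The mean of the mesoderm list was positive (0.06) and its median was not (-0.02). The mean of the neural crest list was positive (0.12) against a median of -0.15, and the fibroblast list had a mean of -0.39 against a median of 0.09. The call of Bmp4 ended without ES 2, ES 3, day 4 or day 5 (highest adjusted p 0.148). That of Lamc1 ended without any single array but day 5 and with no filter (0.1), and that of Foxd3 without ES 2 (0.0879). Without day 3, 1 endoderm, 1 fibroblast and 2 neural crest genes rose, and without ES 1, 2 fibroblast genes fell.

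Among signalling lists, Notch pathway genes passed camera upward with the preset correlation but not with an estimated one. Of 15, 4 rose and 1 fell in limma (the same counts when adjusted over the list alone), and 10, with Hes5 among them, did not pass. The feedback inhibitor Nrarp (108954_at, 2.94), Lfng (114102_at, 1.46), a glycosyltransferase that modifies Notch, the ligand Jag1 (1.44) and Notch3 (1.38) rose, and Dtx1 (102924_at, -0.90) fell (camera adjusted p 0.0122, and 0.298 with an estimated correlation). Of 9 nodal pathway genes, the co-receptor Tdgf1 (93002_r_at, -2.87) and Smad7 (92216_at, -0.99) fell and the receptor Acvr2b (93903_at, from 1180 to 2548) rose (2 rises and 3 falls when adjusted over the list alone; camera adjusted p 0.0309, and 0.332 with an estimated correlation). Of 10 hedgehog pathway genes, the co-receptors Boc (117276_at, 2.47) and Gas1 (94813_at, 2.03) rose and 0 fell (3 rose when adjusted over the list alone; camera adjusted p 0.0164, and 0.298 with an estimated correlation). Of 10 Wnt targets, the Wnt antagonists Sfrp1 (114303_at, 3.28) and Sfrp2 (93503_at, 2.89) and the receptor Fzd7 (0.95) rose, and Notum (114407_at, -1.93), an extracellular Wnt inhibitor, and Myc (104712_at, -1.64) fell (4 rises and 2 falls when adjusted over the list alone; camera adjusted p 0.0495, 0.396 with an estimated correlation and 0.182 with the mean over the probe sets of a gene). Of 13 BMP targets, Id2 (93013_at, 2.73), Id1 (100050_at, 1.59) and Id4 (1.56) rose, and Smad7 and Bmp4 fell (3 and 2 when adjusted over the list alone; camera adjusted p 0.817). Of 17 FGF-ERK targets, Fgf15 (97721_at, 1.93) and Fgfr2 (93090_at, 1.11) rose, and Etv5 (163173_at, -2.21), Fgf4 (98826_at, -1.79) and Spry4 (-1.28) fell (2 and 3 when adjusted over the list alone; camera adjusted p 0.898). Camera pointed down while the median (0.03) and mean (0.01) were positive. The nodal list changed sign between days, with a median against ES cells of 0.49 on day 3 and -0.83 on day 4. In the hedgehog list Foxa2 (1.73) and Nkx2-2 (2.10) passed the filter only through their day 5 values, which favours a rise of that list in camera.

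Several of these calls depended on single samples. Without ES 2, 2 Notch genes rose, 1 nodal gene fell, 0 nodal genes rose, 0 BMP targets fell and 0 FGF-ERK targets rose. Without ES 3, 2 Notch genes rose, 1 nodal gene fell and 0 BMP targets fell. Without day 3, 1 Notch gene rose. Without day 4, 1 nodal gene fell, 0 nodal genes and 1 FGF-ERK target rose, 1 hedgehog gene rose and 0 BMP targets fell. Without day 5, 2 Notch genes rose, 0 nodal genes rose and 0 BMP targets fell. The call of Dtx1 ended without ES 1, ES 2, ES 3, day 4 or day 5 (highest adjusted p 0.16), Lfng without ES 3, day 3 or day 5 (0.112), Smad7 without any single array but ES 1 (0.112) and Acvr2b without ES 2, day 4 or day 5 (0.0841). That of Boc ended without day 4 (0.0929), Fgf15 without ES 2 (0.0571), Fgfr2 without ES 2 or day 4 (0.0596), and Id1 without ES 3 and day 5 together (0.0595).

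Most genes of DNA methylation and chromatin, of imprinted loci and of the p53 response did not pass in limma, but some did. Of 23 chromatin genes, 15 did not pass, 6 fell and 2 rose (7 and 2 when adjusted over the list alone). Tet1 (133204_at, -3.41) and Tet2 (-2.22), which oxidise methylcytosine, and Dnmt3l (113451_at, -2.81), a cofactor of de novo methylation, fell, and Hmga2 (99058_at, 3.02) and Tet3 (105822_at, 1.48) rose (camera adjusted p 0.0337, and 0.332 with an estimated correlation). Of 16 imprinted genes, Nnat, Ndn (101059_at, 2.82), Plagl1 (2.60), Mest (2.28) and Sgce (1.90) rose, Phlda2 (104548_at, -2.01) fell and 10 did not pass (the same counts when adjusted over the list alone; camera adjusted p 9.1e-05, and 0.332 with an estimated correlation). Of 13 p53 response genes, 5 fell, 0 rose and 8 did not pass (6 and 1 when adjusted over the list alone), among them Perp (97825_at, -2.11) and Plk2 (92310_at, -1.79), while the p53 target Cdkn1a had -0.08 with a limma adjusted p of 0.92 (camera adjusted p 0.00596, and 0.332 with an estimated correlation). Of 17 immediate early and heat shock genes, Fos (160901_at, 1.99) and Fosb (103990_at, 1.19) rose and Ier3 (94384_at, -0.86) fell (2 rises and 2 falls when adjusted over the list alone; camera adjusted p 0.898). Of 26 cell cycle genes, Rrm1 (100612_at, 0.75) rose, Cdc20 (96319_at, -0.77) and Ccne1 (103034_at, -0.68) fell, and 23 did not pass (1 and 4 when adjusted over the list alone; camera adjusted p 0.471). Of 15 hypoxia response genes, the kinase Pdk1 (100977_at, -1.74) fell (1 when adjusted over the list alone; camera adjusted p 0.823, pointing down with a median of 0.00). None of the 15 glycolysis, 15 cholesterol synthesis or 16 oxidative phosphorylation genes passed in limma, also when adjusted over the list alone (camera adjusted p 0.817, 0.898 and 0.238; cholesterol synthesis pointed down with a median of 0.02).

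The p53 falls were 2 without ES 1 or ES 2 and 3 without ES 3, and the call of Perp ended without ES 1 or ES 2 (highest adjusted p 0.085). The call of Phlda2 ended without ES 1, ES 2, ES 3, day 4 or day 5 (0.126), Rrm1 without the same arrays (0.217), Ccne1 without any 1 array (0.153), and Cdc20 and Ier3 without any single array but ES 1 (0.182 and 0.249). That of Fos ended without ES 2, ES 3 or day 4 (0.0858) and that of Fosb without ES 2, ES 3, day 4 or day 5 (0.135). Without ES 3 and day 5 together those of Plk2 (0.0639) and of Zic5, of the epiblast list (0.0539), ended. Without ES 1, 1 hypoxia gene rose, and without ES 3, 1 cholesterol synthesis gene rose.

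Day 1 cells were compared with ES cells to show the first changes in the aggregates. Of 25690 probe sets limma called 0, with 1625 at an unadjusted p under 0.05, and 1803 differed by 1 or more on the log2 scale, against 1443 to 2544 for 1 ES sample against the mean of the other ES samples. The pluripotency list had a median of -0.17, with 11 of 32 genes at or above their ES level, 15 lower by less than 1 and 6 lower by 1 or more. These 6, chosen after their values were seen, were Klf4 (423 against 1854 to 3339 in the ES arrays, a log2 difference of -2.47), Socs3 (200 against 646 to 1480, -2.12), Tbx3 (-1.76), Esrrb (3996 against 10660 to 16890, -1.72), Klf5 (-1.51) and Tfcp2l1 (-1.18); their limma adjusted p lay between 0.446 and 0.614. List medians were set against 10000 random gene lists of the same size and signal level, which measures their place among genes and not their spread between cultures. The epiblast list had a median of 0.38 (percentile 99.9), Wnt targets 0.44 (99.9), p53 response 0.36 (99.8) and neural crest genes 0.35 (99.1), while immediate early and heat shock genes had -0.34 (percentile 0.175), fibroblast genes -0.48 (0.29), endoderm genes -0.24 (1.45), Notch genes -0.25 (2.21) and pluripotency genes -0.17 (1.27). Neural progenitor genes had a median of 0.15 (percentile 96.0), with 10 of 37 higher and 1 lower by 1 or more. Over all 12932 genes 312 were higher and 371 lower by 1 or more, and these counts were not tested. Single ES arrays had medians of similar size for some lists, -0.44 to 0.18 for epiblast and -0.08 to 0.32 for neural crest genes. For other lists they were smaller: -0.09 to 0.16 for fibroblast, 0.01 to 0.03 for endoderm and -0.12 to 0.02 for pluripotency genes. Each ES array was part of the mean it was set against and day 1 was not, which makes the ES values too small. The ES values therefore cannot show that day 1 lay beyond the spread of ES cells. Without ES 1 the count of calls was 72.

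Day 2 E-cadherin-positive cells kept Pou5f1 at 11900, above the ES arrays (6836 to 8778), and limma called 0 probe sets against ES cells, with 2087 at an unadjusted p under 0.05. Hypoxia response genes were higher, with a median log2 difference of 0.94 (percentile 100) and 6 of 15 at 1 or more: the oxygen sensor gene Egln3 had 2.24, Car9 1.42 and Bnip3 1.41 (adjusted p above 0.05 in limma). Glycolysis genes had a median of 0.44 (percentile 100), with Pgk1 at 1.16, and immediate early genes 0.42 (100), with Fos at 4397 against 389 to 712 in ES arrays. Epiblast genes had 0.52 (percentile 100), with Dnmt3b at 7129 against 1804 to 3075 in ES arrays. Nodal pathway genes had 0.38 (99.3), Wnt targets 0.38 (99.5), BMP targets -0.33 (0.64), cell cycle genes -0.14 (2.52) and pluripotency genes -0.14 (3.16). Of 32 pluripotency genes 7 were lower by 1 or more, among them the 6 that were lower on day 1 (median -1.62). Neural progenitor genes had 0.08 (80.9) and neuronal genes -0.08 (16.5). The genes named for this sample were chosen after their values were seen. Without ES 1 the count of calls was 92.

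In day 3 Sox1-negative cells limma called 0 probe sets against ES cells, with 1709 at an unadjusted p under 0.05, and Pou5f1 was at 7075. Epiblast genes had a median log2 difference of 1.05 (percentile 100), with 8 of 15 at 1 or more, among them Wnt8a (2.34), Pim2 (1.77) and Dnmt3b (7483 against 1804 to 3075 in ES arrays). Hypoxia response genes had 0.67 (100), glycolysis genes 0.61 (100), immediate early and heat shock genes 0.50 (100), nodal pathway genes 0.56 (100), Wnt targets 0.57 (100), Notch genes 0.25 (97.4) and cholesterol synthesis genes 0.19 (97.0). Notch and cholesterol synthesis genes had medians below 0 in day 2 E-cadherin-positive cells, -0.11 (percentile 19.8) and -0.09 (15.7), and BMP targets had -0.11 (12.01) on day 3. Pluripotency genes had -0.25 (percentile 0.04), with 8 of 32 lower by 1 or more, and neural progenitor genes 0.10 (77.8). The genes named for this sample were chosen after their values were seen. Without ES 1 the count of calls was 116.

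The day 2 E-cadherin-negative cells, 1 sample, were compared with ES cells as well. Nnat (5826 against 149 ± 28.0 in ES cells, n = 3) and Crabp1 (6659 against 318 ± 31.2) rose by 5.16 and 4.33 on the log2 scale, each with a limma adjusted p of 0.0105, and Zfp42 (275 against 3543 ± 695) fell by 3.60 (0.0446). These were the genes among 7 called probe sets, 5 higher and 2 lower, with 3506 at an unadjusted p under 0.05. These p-values rest on the spread between the ES samples and say nothing on the variation between samples of E-cadherin-negative cells. Pluripotency genes had a median of -1.33 (percentile 0), with 20 of 32 lower by 1 or more, and epithelial genes -0.79 (0). Neural progenitor genes had 1.30 (percentile 100), with 24 of 37 higher by 1 or more, mid-hindbrain and caudal genes 1.35 (100), neuronal genes 0.80 (100), imprinted genes 0.69 (100), mesenchymal genes 0.71 (99.8), retinoic acid response genes 0.72 (100), epiblast genes 0.82 (100), hypoxia response genes 0.47 (99.7), immediate early genes 0.39 (99.6), FGF-ERK targets 0.31 (98.8) and Notch genes 0.40 (98.3). P53 response genes had -0.62 (0.03), nodal pathway genes -0.51 (0.39), germ cell genes -0.36 (0.64), cell cycle genes -0.28 (0.31) and chromatin genes -0.28 (1.04). The count of calls was 473 without ES 1, 0 without ES 2, 11 without ES 3 and 0 with no filter; this sample also had an actin ratio of 1.33.

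The sorts of day 2 and day 3 were each compared within their day, with 1 sample on a side and so no test. On day 2 the E-cadherin-negative cells had higher Crabp1 (6659 against 136, a log2 difference of 5.46), Ednrb (889 against 13.8, 4.92), Hoxa2 (1409 against 35.2, 4.80), the neuronal transcription factor Nhlh2 (166814_f_at, 4781 against 182, 4.60), Hoxa3 (4.58), Pou3f3 (4.00), Tshz1 (106265_at, 3.85), Dach1 (3.83), Nnat (3.69) and Cnmd (165981_i_at, 3.66). They had lower Ccno (114581_at, -3.69), the interferon-induced Gbp2b (95974_at, -3.50) and Ifi35 (100013_at, -3.22), Gchfr (168197_r_at, -3.49), Serpinb9b (166976_at, -3.22), Cldn6 (-3.13), Calhm6 (135693_at, -3.10), Gm19705 (134141_at, -3.10), Shfl (114836_at, -3.02) and Rarg (-3.02). Of these 20 genes 14 had a lower value under the filter level of their chip (78.6, 117 or 102), so the size and order of their differences depend on the pseudocount: Ednrb had 5.91 with a pseudocount of 1 and 3.61 with 64. Cdh1 message itself was alike, at 565 and 573, and Sox1 was at 251 and 253. Of 25690 probe sets 3484 differed by 1 or more, 1980 higher and 1504 lower, against 2104 to 3569 between pairs of ES samples. This count lay above the range between ES samples under quantile normalization (3625 against 2014 to 3420) and with a filter at the 60th percentile (1430 against 547 to 1361). At 2 or more there were 603, against 306 to 566, but the count lay within the range with a pseudocount of 1 (813 against 527 to 907) and with no filter (879 against 461 to 906). Pluripotency genes had a median of -1.10 (percentile 0), epithelial genes -0.84 (0), nodal pathway genes -0.89 (0), glycolysis genes -0.45 (0.05) and immediate early genes -0.46 (0.01). Neural progenitor genes had 1.17, mid-hindbrain genes 1.28, neuronal genes 1.26 and imprinted genes 1.05 (percentile 100 each), with 14 of 23 neuronal genes higher by 1 or more.

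On day 3 the Sox1-positive cells had higher Crabp1 (11400 against 159, a log2 difference of 6.03), Nr2f1 (852 against 6.89, 5.25), Ednrb (5.20), Hs3st3b1 (116617_at, 5.15), Irx1 (130122_f_at, 4.99), Pea15a (100548_at, 4.91), Hoxa3 (4.55), Dach1 (4.35), Cpne2 (165583_i_at, 4.17) and Eml1 (117201_at, 4.10) than Sox1-negative cells. They had lower Esrrb (68.2 against 5190, -5.95), Ccno (-4.72), Cldn6 (129 against 3794, -4.72), Dusp27 (-4.71), Zfp42 (-4.64), B3gnt2 (-4.46), Tbx3 (-4.29), Nr0b1 (93141_at, -4.28), Fbxo15 (-4.25) and Inpp5d (-4.06). Of these 20 genes 15 had a lower value under the filter level of their chip, and their differences depend on the pseudocount in the same way: Nr2f1 had 6.76 with a pseudocount of 1 and 3.69 with 64. Sox1 was at 308 against 241. Of the 25690 probe sets 3949 differed by 1 or more, 1953 higher and 1996 lower, above the range between ES samples (2104 to 3569), and 830 differed by 2 or more, against 306 to 566. Of 32 pluripotency genes 26 were lower by 1 or more (percentile 0). Epithelial genes had a median of -1.12 (0), germ cell genes -1.16 (0.01), epiblast genes -0.53 (0.01), hypoxia response genes -0.63 (0.05), p53 response genes -0.48 (0.16) and chromatin genes -0.48 (0). Neural progenitor genes had 1.48, mid-hindbrain genes 0.89, neuronal genes 0.43, retinoic acid response genes 0.60, imprinted genes 0.43 and mesenchymal genes 0.67 (percentiles from 99.6 to 100).

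The sort differences of the 2 days, which share no sample, went the same way for most genes that moved in both; this comparison was added after the data were seen. Across the 6466 genes at or above the median signal level, Pearson's r was 0.64 and Spearman's rho 0.54 (0.46 and 0.40 over all 12932 genes), where genes are not independent replicates. Of these 6466 genes 142 were higher by 1 or more in both sorts, against 10.4 if the sorts were independent, 123 were lower in both, against 9.97, and 2 went opposite ways. Over all 12932 genes 365 were higher in both, 266 were lower in both and 83 went opposite ways, 58 of them on U74Cv2. On U74Av2, U74Bv2 and U74Cv2 Pearson's r was 0.57, 0.54 and 0.30 over all tested genes, and 0.72, 0.68 and 0.53 over those at or above the median signal level.

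**Figure D3:**
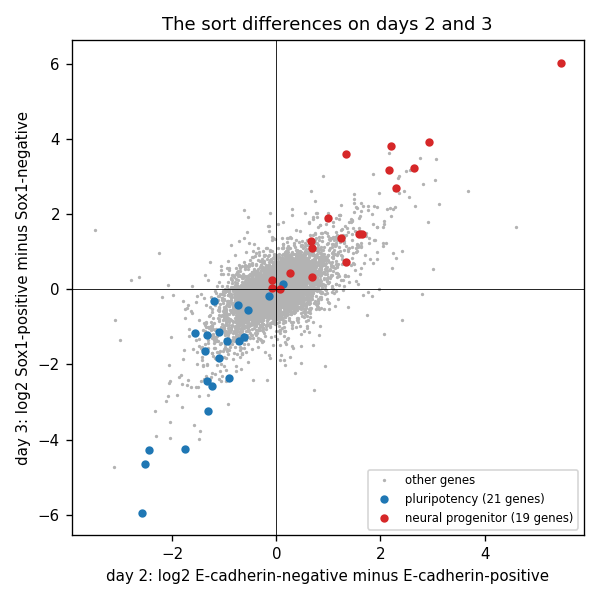
Log2 difference of E-cadherin-negative minus E-cadherin-positive cells on day 2 (x axis) against Sox1-positive minus Sox1-negative cells on day 3 (y axis); each point is 1 gene, of the 6466 at or above the median signal level. The 142 genes higher and the 123 lower by 1 or more in both sorts lie in the upper right and lower left, with most pluripotency genes low and most neural progenitor genes high in both.

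The Sox1-positive samples of days 3, 4 and 5 were used to look for change after the onset of Sox1. Limma called 0 of 25690 probe sets for a slope on day, with 2105 at an unadjusted p under 0.05, so the genes below are given as values and were chosen after these were seen. Neuronal genes had a median slope of 0.47 on the log2 scale per day (camera adjusted p 2.22e-06, and 0.609 with an estimated correlation): Nhlh2 was at 629, 1483 and 5140 on days 3, 4 and 5, Map2 at 346, 430 and 1576, and Neurod4 at 41.5, 109 and 556. Hedgehog pathway genes had a median slope of 0.74 (camera adjusted p 0.000472, and 0.609 with an estimated correlation) through a step on day 5. The hedgehog ligand gene Shh was at 98.8, 75.1 and 708, and the receptor Ptch1 at 2268, 2111 and 6312. Nkx2-2 was at 54.6, 64.1 and 1908, and Foxa2 at 55.3, 51.5 and 1315. These last genes passed the filter only through their day 5 values, which lifts the list's slope. Nodal pathway genes had a median of -0.10 (camera adjusted p 8.98e-08, and 0.609 with an estimated correlation), the nodal antagonist Lefty1 being at 36270, 16850 and 1157 and Lefty2 at 1436, 418 and 14.7. Epiblast genes had a median of -0.42 (4.04e-07), pluripotency genes -0.15 (1.27e-05), epithelial genes -0.12 (0.0186) and p53 response genes -0.13 (0.0201), and neural progenitor genes 0.22 (0.00174), each with a camera adjusted p of 0.609 with an estimated correlation, and glycolysis genes -0.18 (0.0374, and 0.665). Day 5 had the highest actin ratio of these 3 samples (1.34, against 0.993 on day 3 and 1.15 on day 4).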

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

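No paired analysis was possible, because every group but the ES cells had 1 sample and no label says which samples shared a culture. For Sox1-positive against ES cells, 2036 to 3234 probe sets were called over the settings other than leaving samples out (2710 as reported). Leaving out 1 sample gave 1233 (without ES 2) to 2162 (without ES 1), and leaving out ES 3 and day 5 together, an alternative added after the data were seen, gave 1055. Of the 1233 calls without ES 2, 1179 were among those reported. Per gene, the mean over all probe sets called 1895 genes, of which 1396 were among the 1626 reported. Against ES cells, day 1 had 0 calls as reported, 1 with a pseudocount of 64, 1 with a filter at the 60th percentile, 1 with adjustment within each chip, and 0 to 72 with an ES sample left out. Day 2 E-cadherin-positive cells had 0 as reported and 1, 4 and 1 under the same settings, and 0 to 92 with an ES sample left out. Day 2 E-cadherin-negative cells had 7 as reported, 4 with a pseudocount of 1, 131 with a pseudocount of 64, 0 with no filter, 231 with a filter at the 60th percentile, 166 with a mean-variance trend, 59 with adjustment within each chip, and 0 (without ES 2) to 473 (without ES 1). Day 3 Sox1-negative cells had 0 as reported, 3 with a pseudocount of 64, 7 with a filter at the 60th percentile, 3 with a mean-variance trend, 3 with adjustment within each chip, and 0 to 116 with an ES sample left out. The slope on day had 0 as reported, 2 with a pseudocount of 64 and 0 to 1 with an ES sample left out. Between the day 2 sorts 3484 probe sets differed as reported, 603 at a threshold of 2, 5735 with no filter and 1430 with a filter at the 60th percentile; between the day 3 sorts these were 3949, 830, 6461 and 1654. Of 31 gene lists 18 passed as reported, 18 under quantile normalization, 16 with the mean over probe sets (without the epiblast list and the Wnt targets) and 0 with an estimated correlation. The count at a higher threshold, or with more or fewer probe sets tested, differs by construction; for the other differences the cause was not tested. Under quantile normalization the share of higher probe sets among those that differed by 1 or more went from 49.5% to 51.7% between the day 3 sorts and from 56.4% to 49.5% in day 2 E-cadherin-negative against ES cells. Of the 82 genes named as called in Sox1-positive cells, 0 changed direction in a setting that gave them a value. Leaving out samples could not reverse them, since their ES and Sox1-positive arrays did not overlap. The calls lost were 10 without ES 1, 26 without ES 2 and 18 without ES 3. They were 11 without day 3, 23 without day 4 and 18 without day 5.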

Other observations

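The genes called in Sox1-positive cells with a change of 1 or more on the log2 scale can be used as a scale on which each sample has a place, with 0 for the ES mean and 1 for the Sox1-positive mean; this was chosen after the data were seen. Day 2 E-cadherin-negative cells had a median place of 0.70 for 617 genes that rose, such as Crabp1, and 0.67 for 596 that fell, such as Esrrb. Day 2 E-cadherin-positive cells were at 0.12 and 0.23, day 1 cells at 0.13 and 0.12, and day 3 Sox1-negative cells at 0.18 and 0.21. With a single ES sample as the zero, the place for rising genes was 0.54 to 0.80 for the E-cadherin-negative cells, 0.0177 to 0.22 for E-cadherin-positive, -0.00258 to 0.22 for day 1 and 0.0653 to 0.27 for Sox1-negative cells. The ES arrays themselves lay at -0.15 to 0.15 for rising genes, a range that holds the day 1 and E-cadherin-positive places. For falling genes the ES arrays lay at -0.00792 to 0.0113. With a single ES sample as the zero, day 1 cells were at 0.0958 to 0.108 and E-cadherin-positive cells at 0.193 to 0.217. Sox1-negative cells were at 0.176 to 0.199 and E-cadherin-negative cells at 0.637 to 0.643. Both versions used genes called with all 3 ES arrays, a choice that favours genes with a small ES spread. The ES places therefore cannot decide whether a sample outside that choice, such as day 1, lies beyond the spread of ES cells.

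Individual ES arrays differed at some genes, chosen after their values were seen: Gbx2 was at 234, 2296 and 2727, Acta2 at 216, 2490 and 1760, and Sox11 at 402, 2916 and 4525 on the arrays of ES 1, ES 2 and ES 3. The difference was not limited to these genes. ES 1 differed by 1 or more on the log2 scale from ES 2 at 2594 probe sets and from ES 3 at 3569. It differed from day 1 cells at 2529 and from day 3 Sox1-negative cells at 2710. The pair of ES 1 and ES 3 sets the upper end of the range between ES samples. Such differences enter the spread of every comparison with ES cells, and the cause was not tested. Egln3, a hypoxia response gene, was at 3706 on day 2 E-cadherin-positive, 3108 on day 2 E-cadherin-negative and 2787 on day 3 Sox1-negative arrays, against 470 to 1504 in ES cells.

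The 6 samples of the largest comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2710 probe sets and the highest other 1, and 1 of the 10 splits reached the real count. This test was chosen before the result was seen.

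Klf4, Klf5, Esrrb, Tbx3, Tfcp2l1 and Socs3 were lower by 1 or more in day 1 cells, while of the other 26 pluripotency genes 15 were lower by less and 11 were at or above the ES level. Less LIF and STAT3 signalling might explain this: a list of their targets, chosen before its values were seen, had a median log2 difference of -0.49, at percentile 0.03 of random lists, with 10 of 13 genes lower, such as Pim3 (802 against 1635 to 1920) and Bcl3 (-0.94). Neither pattern was particular to day 1. The 6 genes had a median of -1.62 in day 2 E-cadherin-positive and -1.49 in day 3 Sox1-negative cells. The list of targets had -0.71 (percentile 0) and -0.27 (0.73) in these samples. A mixed sample of day 1 with Sox1-positive cells is argued against, in a test chosen after the result was seen. The falls of the 6 would need a share of such cells of 0.60 or more, but the day 1 intensities of the 617 genes called with a rise of 1 or more in Sox1-positive cells gave a median share of 0.0556 (quartiles -0.0411 and 0.192). A mixture with cells of another kind stays open. No gene of the 6 passed in limma on day 1, and the composition of the medium was not measured.

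Of 10 hedgehog pathway genes 6 were higher by 1 or more on the day 5 Sox1-positive arrays and 3 were lower (Gli2 -1.02, Gli3 -0.70 and Gas1 -0.40), which may come from floor plate-like or other ventral neural cells. Nkx2-2 and Foxa2, among the raised genes, lay under their chip's filter level (78.6) in all other samples. They were tested only through their day 5 values, so the count of raised genes partly follows from the filter. A list of floor plate and ventral neural tube genes, chosen before its values were seen except that 1 of its genes (Gata2) was also in a list already examined, and with 7 of its 17 genes tested, had a median of 1.12 on day 5 against days 3 and 4, at percentile 100 of random lists (1.51 and 100 without Gata2), with Nkx6-2 at 2140 against 119 and 145. It does not tell floor plate cells from other ventral cells that respond to hedgehog. The next 2 tests were chosen after the result was seen. Endoderm cells in the sorted sample, which also express Foxa2, were not decided on. The sort for Sox1-GFP should leave few of them, but its purity was not measured. The median of the endoderm list without Foxa1 and Foxa2 was -0.00031, but 3 of 19 genes (Pth1r, Lamc1 and Sox17) were higher by 1 or more. A fault of a single array is argued against, as the 6 raised hedgehog genes lay on all 3 chips.

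Day 2 E-cadherin-negative cells lay close to Sox1-positive cells, and the tests here were all chosen after the result was seen. A mixture of ES cells and day 3 Sox1-positive cells alone is argued against, since 5 of 23 neuronal genes (Dcx, Map2, Neurod4, Nhlh1 and Nhlh2) were higher than in both by 1 or more, against a median of 0 in random lists. RNA of one of the Sox1-positive samples under another name is argued against too: 16 to 21 of 32 pluripotency genes lay 2-fold apart from each of these samples, all higher in the E-cadherin-negative cells, against at most 4 between ES samples. An earlier measure, the count of probe sets 2-fold apart (at least 2506, against 2394 to 3292 among Sox1-positive samples), had not separated them. Of the 5 neuronal genes 4 were higher still on day 5 (Nhlh2 at 5140 against 4781, and 238.3 in ES cells). A mixture of ES cells with the whole day 5 sample is argued against. Of the 4 genes Nhlh2 would need mostly day 5 cells, but Neurod4 fewer, at 216 against 556 and 40.4 in ES cells. Nhlh1 was at 3328, above its day 5 value of 2870. The hedgehog list had a median log2 difference from ES cells of 0.07, against 1.75 on day 5. Ptch1 was at 1894 against 6312 and Hhip at 398.9 against 1214, while Boc (1.323) and Gas1 (1.549) were raised. A mixture with only some of the day 5 cells stays open.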
